A study of Mus musculus with 4 samples.

How the data were processed

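RNA from MEFs infected with a GFP lentivirus (GFP control, 2 libraries) or with the lentivirus of Stella, Oct4 and Nanos2 (SON, 2 libraries) was prepared by the authors with the TruSeq mRNA kit v2, whose reads carry no strand. Groups and replicate numerals were taken from the sample titles. The notes of the submitters name CASAVA 1.8.1, TopHat2 2.0.11, HTSeq 0.5.3p3, STAR 2.4.0j, featureCounts, Subread and DESeq2, with the genome GRCm38 (mm10), and do not state which tool made which table. The labels do not say whether the 2 libraries of a group come from separate cultures or embryos, so p-values measure the spread between these libraries. Infection with each virus and the culture of its cells coincide with the groups and could not be separated from the delivered genes.

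The deposited gene table holds a signal per gene and library for 39179 Ensembl genes. The authors made it by dividing read counts by 1 size factor per library, as the values show: every value was a whole multiple of 1 step per library within a tolerance of 0.01 reads. Per the file headers the same deposited table holds DESeq2 columns of the authors: the mean signal, the log2 fold change with its standard error, the Wald statistic as a score, and the p-value with its adjusted form. These columns were used as the authors' own comparison only. The deposited table of repeats holds a signal for 36284 repeat copies with 1040 RepeatMasker names, again reads divided by 1 factor per library. It spans all repeat classes and not LTR elements alone, and its copies had at least 21 reads over the 4 libraries, with a median of 36. How reads with several hits were counted is not given in the sources used here. Its columns name the group and a letter. No label joins the letters to the numerals I and II, and values were not used to assign columns to samples, so the columns were used by group. The size factors were 1.20 and 1.68 in the GFP control and 0.736 and 0.680 in SON in the repeat table, and 1.20 and 1.68, and 0.733 and 0.681, in the gene table. Gene names came from the table for 21019 genes and from the GENCODE annotation of GRCm38 alone for 17090 others, and 37607 identifiers matched that annotation, which also gave coordinates and overlaps.

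Dividing each value by the step gave whole reads. The totals in genes were 28924700 and 37097571 for GFP control I and II, and 17365551 and 14680865 for SON I and II. In repeats they were 850223, 1119717, 565399 and 469737. A floor of 3 reads, the limit that a count of 0 allows, was 2.51, 1.78, 4.09 and 4.41 normalized counts in the 4 gene columns. For the delivered genes a ratio with 1 GFP control read was given with an exact (Clopper-Pearson) 95% interval. A ratio with 0 reads was given against the floor over the group, with the lower limit of the exact interval. No pair of libraries was a copy of another: the chi-square per degree of freedom between their reads was at least 48.2.

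Because the files hold normalized values, the test fixed for that case was used: limma 3.58.1 in R 4.3.3 on log2 of the value plus a pseudocount of 1, with a trend on the mean, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Genes were filtered with filterByExpr of edgeR 4.0.16 on the group, which left 15283 genes, while 13132 genes had no reads in any library. The same fit was made for 17390 repeat copies and for 943 repeat names after summing their copies, 469 of them LTR names. Gene lists with at least 5 tested members, 21 in number, were tested with camera of limma (preset correlation 0.01, two-sided, adjusted over the lists) on the same values in place of the planned log CPM, which served as an alternative. Camera with an estimated correlation and fry were run beside it. Pluripotency and chromatin silencing shared 1 tested gene. H2-L, Kcnq1ot1 and Hoxd4 were not found in the table by name. Over the deposited scale and TMM, RLE and upper-quartile factors, the median log2 difference of all tested genes lay between -0.01 and 0.02.

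The main test, the lists, the alternatives and a rule for naming genes were fixed before the data were examined. The rule names the delivered genes, the 6 largest rises and falls among the calls with at least 5 CPM (counts scaled to a common library size) and separated groups, without predicted genes, and in each list up to 3 called members or else the member with the most reads. For LTR names it takes the 4 largest rises and falls. Not every gene that the rule takes is given in the text. Genes named from the authors' deposited table (up to 4 members per list with the smallest adjusted p, and examples of the 12 largest rises and falls) were chosen after their values had been seen, as were the sums shown for the IAP and MERVL names.

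Alternatives were pseudocounts of 0.1 and 10, no filter, a filter of 1 CPM in 2 libraries, a minimum log2 difference of 1, and each library left out in turn. On the recovered reads DESeq2 1.42.0, limma voom and edgeR with RLE or upper-quartile factors were run, as was a replicate block in edgeR. Added after the data had been seen were limma with TMM factors (prior count 2 for log CPM), the replicate block in limma and DESeq2 without each library. The repeat table without its ribosomal RNA was also added then. EdgeR with TMM factors had been fixed beforehand as the main test for raw counts, and camera on log CPM as the test of the lists. Their use as alternatives on the recovered reads was chosen after the data had been seen. With groups of 2, no library could be tested as an outlier and no count over other groupings was made.

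The tests were tested on simulated data of the same depths with dispersions from a trend, which vary less than real genes. Genes were drawn independently, so these data cannot show false calls of camera in lists of correlated genes. Estimated correlations in the real lists ran from -0.15 (pluripotency) to 0.89 (cell division), with 0.70 for interferon-stimulated genes, against the preset 0.01. Of 50 genes changed at each size, limma recovered 32% at 2-fold, 98% at 4-fold and 100% at 8-fold and 16-fold, with 6 false calls among 15283 genes. For repeat copies it recovered 4%, 60%, 98% and 100%, with 2 false calls among 17390. On a simulated list of 40 shifted genes camera gave p = 8.27e-51, fry p = 0.00134 and camera with an estimated correlation p = 0.005. All of these tests called 0 of 20 unshifted lists. Adjusted over these lists, camera with an estimated correlation missed the shifted list, so a lack of calls by it is weak evidence of no difference.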

Results

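Messenger RNA was sequenced from BALB/c mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, in 4 libraries that formed 2 groups of 2. The SON cells carried a lentivirus with Stella (gene Dppa3), Oct4 (gene Pou5f1) and Nanos2, all genes of the germ line or the early embryo. The GFP control cells carried a lentivirus with green fluorescent protein. Selection with 2 µg/ml puromycin started 72 h after infection at passage 2 and took 4 days, and 21 days of culture without the drug followed. The reads recovered in genes came to 28924700 in GFP control I, 37097571 in GFP control II, 17365551 in SON I and 14680865 in SON II. In annotated repeats they came to 850223 and 1119717 in the GFP control libraries and to 565399 and 469737 in the SON libraries. Values are normalized read counts (reads divided by 1 size factor per library), given as the mean ± SD with n = 2 per group, GFP control first. Positions refer to GRCm38. The comparison that the labels define, SON against GFP control, asks what else differed in fibroblasts that received the 3 factors.

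The 3 delivered genes were read in both SON libraries and hardly at all in the GFP control. Pou5f1, which encodes the pluripotency factor Oct4 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), had 0 reads in both GFP control libraries and 329 and 290 reads in the SON libraries. Its SON level was 437 ± 15.99, or 420-fold higher against a floor of 3 reads over the GFP control group (limma adjusted p = 0.0311). The exact 95% interval of its ratio had a lower limit of 341. Dppa3, which encodes the maternal and germ cell protein Stella (ENSMUSG00000046323, chromosome 6, 122626410 to 122630272), had 1 read in the GFP control and rose to 317 ± 30.3. The ratio was 914 (exact 95% interval 163 to 36190, limma adjusted p = 0.0326). Nanos2, which encodes an RNA-binding protein of male germ cells (ENSMUSG00000051965, chromosome 7, 18987400 to 18988962), had 1 read in the GFP control and rose to 383 ± 27.2. Its ratio was 1102 (exact 95% interval 197 to 43590, limma adjusted p = 0.0326). Intervals and floors cover counting error only. The pseudogene Dppa3-ps had 0 reads in the GFP control and 12 and 9 reads in SON, and Pou5f1 and Nanos2 overlap the antisense genes Gm19553 and Gm45058, from which reads without strand cannot be separated.

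Beyond the delivered genes, limma called 5 genes. Col2a1, the type II collagen of cartilage (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695), rose from 28.5 ± 3.36 to 788 ± 211, or by 4.72 ± 0.29 (SE) on the log2 scale (limma adjusted p = 0.0326). Igfbp2, a secreted protein that binds insulin-like growth factors (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), rose from 1161 ± 69.7 to 4906 ± 233 (log2 2.08, limma adjusted p = 0.0356). Fmo2, a flavin monooxygenase (ENSMUSG00000040170, chromosome 1, 162874317 to 162898726), fell from 862 ± 141 to 41.9 ± 7.21 (log2 -4.33, limma adjusted p = 0.0326). Cxcl3, a chemokine that attracts neutrophils (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), fell from 918 ± 99.97 to 95.8 ± 14.0 (log2 -3.25, limma adjusted p = 0.0356). Crabp1, a retinoic acid binding protein (ENSMUSG00000032291, chromosome 9, 54764748 to 54773110), fell from 7662 ± 98.7 to 1581 ± 98.8 (log2 -2.28, limma adjusted p = 0.0326). With the delivered genes, 5 genes were higher and 3 lower of 15283 tested, against 916 higher and 1004 lower at an unadjusted p under 0.05, where chance gives 764. With limma voom the adjusted p was 0.103 for Col2a1, 0.0551 for Igfbp2 and 0.0995 for Fmo2 and Cxcl3, and with upper-quartile factors in edgeR 0.0549 for Igfbp2 and 0.0517 for Cxcl3, at log2 differences of 4.76, 2.08, -4.34 and -3.26 for Col2a1, Igfbp2, Fmo2 and Cxcl3. Without GFP control I, limma called 0 genes (263 higher and 337 lower unadjusted), without SON I 0 (1088 and 1343) and without SON II 0 (1436 and 1306), while DESeq2 called between 20 and 322 higher and between 34 and 381 lower over all its fits. Without GFP control II, limma called 8 higher and 24 lower, and over the 4 fits with a library left out the log2 difference stayed between 4.44 and 4.99 for Col2a1, 2.02 and 2.14 for Igfbp2, -4.50 and -4.16 for Fmo2, -3.40 and -3.10 for Cxcl3 and -2.34 and -2.21 for Crabp1.

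**Figure D1:**
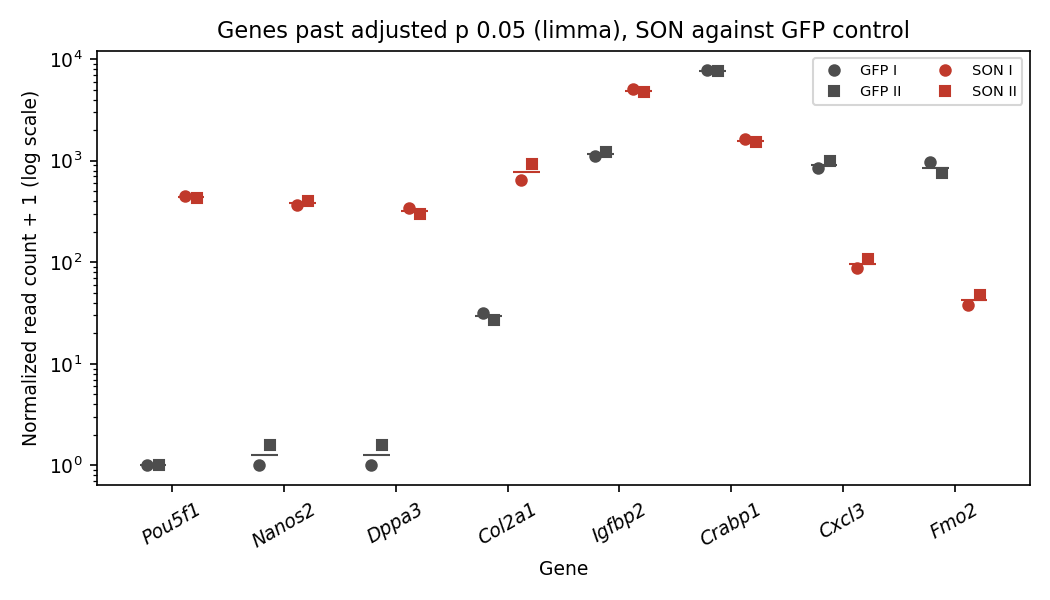
Normalized count + 1 (log axis) of the 8 genes that passed limma at an adjusted p under 0.05, 1 point per library, the line marking the group mean on the log scale. Pou5f1, Dppa3 and Nanos2 lie at 0 or 1 read in the GFP control, and Crabp1 falls from 7662 to 1581.

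The authors' deposited table, made with DESeq2, lists more genes: 217 higher and 379 lower in SON at an adjusted p under 0.05. All 8 genes called by limma are among the 596 in the authors' deposited table, all 596 had the same sign in limma, and 587 had an unadjusted limma p under 0.05. Limma and the authors' DESeq2 used the same libraries, so this overlap is no independent support. Rerun on the recovered reads, DESeq2 called 236 higher and 381 lower, of which 574 were shared with the authors' deposited table, and edgeR called 5 higher and 3 lower. After the limma calls, the largest rises in the authors' deposited table include Map2, a microtubule protein of neurons, Ano1, a chloride channel, and Cobl, an actin nucleator. Map2 measured 80.6 ± 11.2 and 467 ± 20.6, Ano1 28.9 ± 25.5 and 302 ± 149, and Cobl 46.1 ± 33.2 and 316 ± 77.4. Among the largest falls in the authors' deposited table are Rarres2, which encodes the chemoattractant chemerin, Nt5e, a cell surface enzyme that makes adenosine, Mfap4, a microfibril protein, and Hp, the acute-phase protein haptoglobin. Rarres2 measured 2257 ± 1705 and 110 ± 29.8, Nt5e 1971 ± 1769 and 123 ± 46.5, Mfap4 6259 ± 5233 and 454 ± 10.1, and Hp 1449 ± 683 and 141 ± 33.6. DESeq2 without GFP control I called 20 higher and 34 lower, of which 52 were shared with the authors' deposited table. Without GFP control II, DESeq2 called 138 higher and 308 lower, and without SON I it called 149 and 264.

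The libraries also differed within both groups. On the first principal component (56.97% of the variance) GFP control I lay at -58.1 and GFP control II at -18.2, with SON I at 38.8 and SON II at 37.6. The second component (32.9%) parted SON I at 44.7 from SON II at -39.9. Across genes, which are not independent replicates, Pearson's r was 0.983 between the GFP control libraries, 0.968 between the SON libraries and 0.975 between GFP control II and SON II. The difference of GFP control I minus II correlated at -0.50 with that of SON minus GFP control. In the 4859 genes with a mean normalized count of at least 1000 it was -0.63. Genes higher in GFP control I than in II thus tended to be lower in SON. Both differences share the GFP control libraries.

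Interferon-stimulated genes, the antiviral program that interferons switch on, lay lower in SON for all 69 tested members, with a median log2 difference of -1.50 (limma camera adjusted p = 9.29e-40). With an estimated correlation the camera adjusted p = 0.583, and the fry adjusted p was 0.227. No member passed limma over all genes (0 of 69, with 61 lower at an unadjusted p), 61 were lower adjusted over the list alone, and the authors' deposited table calls 50 lower. Ifitm3, which blocks virus entry, measured 16637 ± 3623 and 8365 ± 1144. Among the members that the authors' deposited table calls lower are Oas1g, Oas2, Ifi204 and Trim30a. Oas1g and Oas2, which make the activator of RNase L, measured 217 ± 76.4 and 20.4 ± 5.93, and 451 ± 125 and 76.1 ± 37.0. Ifi204, a DNA sensor, measured 2533 ± 554 and 772 ± 139, and Trim30a 1426 ± 756 and 219 ± 100. GFP control I lay above GFP control II by a median of 0.60, and the list's median was -1.17 without GFP control I. DESeq2 called 52 members lower with all libraries, 3 without GFP control I, 42 without GFP control II, 47 without SON I and 35 without SON II. The 12 markers of macrophages, another cell type that responds to interferon, were also lower, by a median of -0.90.

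The 27 genes of the list on double-stranded RNA sensing had a median of -0.41, with 22 negative and 5 positive (limma camera adjusted p = 6.38e-04, and with an estimated correlation adjusted p = 0.583). The median was -0.22 without GFP control I, with 19 negative. Of these, 2 were lower adjusted over the list alone, 0 passed limma over all genes (2 higher and 8 lower unadjusted), and the authors' deposited table calls 3 lower, Zbp1, Dhx58 and Ifih1. Zbp1, a sensor of Z-form nucleic acid, measured 895 ± 259 and 190 ± 7.98, Dhx58 532 ± 193 and 153 ± 25.9, and Ifih1, the sensor MDA5, 1117 ± 348 and 473 ± 135. Ddx58, the sensor RIG-I, measured 4148 ± 865 and 2539 ± 165. All 21 tested genes of antigen presentation (MHC class I and the immunoproteasome) were lower, with a median of -0.58 (limma camera adjusted p = 2.30e-11, and with an estimated correlation adjusted p = 0.583). Of these, 10 were lower adjusted over the list alone, 0 passed limma over all genes (12 lower unadjusted), and the authors' deposited table calls 8 lower. The class I genes H2-T10, H2-T22 and H2-K1 measured 1669 ± 204 and 565 ± 30.3, 3009 ± 235 and 1123 ± 62.9, and 5921 ± 2563 and 1899 ± 323. The class I gene H2-T23 measured 1351 ± 653 and 454 ± 18.1, and Calr, a chaperone of the same route, 42942 ± 2456 and 38828 ± 7123.

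Cytokines and other genes of inflammation had a median of -1.35 over 38 members, 33 of them negative (limma camera adjusted p = 3.18e-11, and with an estimated correlation adjusted p = 0.583). Of these, 13 were lower adjusted over the list alone, 0 passed limma over all genes (22 lower unadjusted), and the authors' deposited table calls 19 lower. Saa3, an acute-phase protein, measured 136720 ± 66869 and 13014 ± 4825. The chemokines Ccl11 and Cxcl5 measured 9634 ± 3380 and 898 ± 394, and 47631 ± 23093 and 8392 ± 605. Cxcl9, a chemokine induced by interferon gamma, measured 152 ± 157 and 4.25 ± 0.22. The median difference between GFP control I and GFP control II was 0.78.

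**Figure D2:**
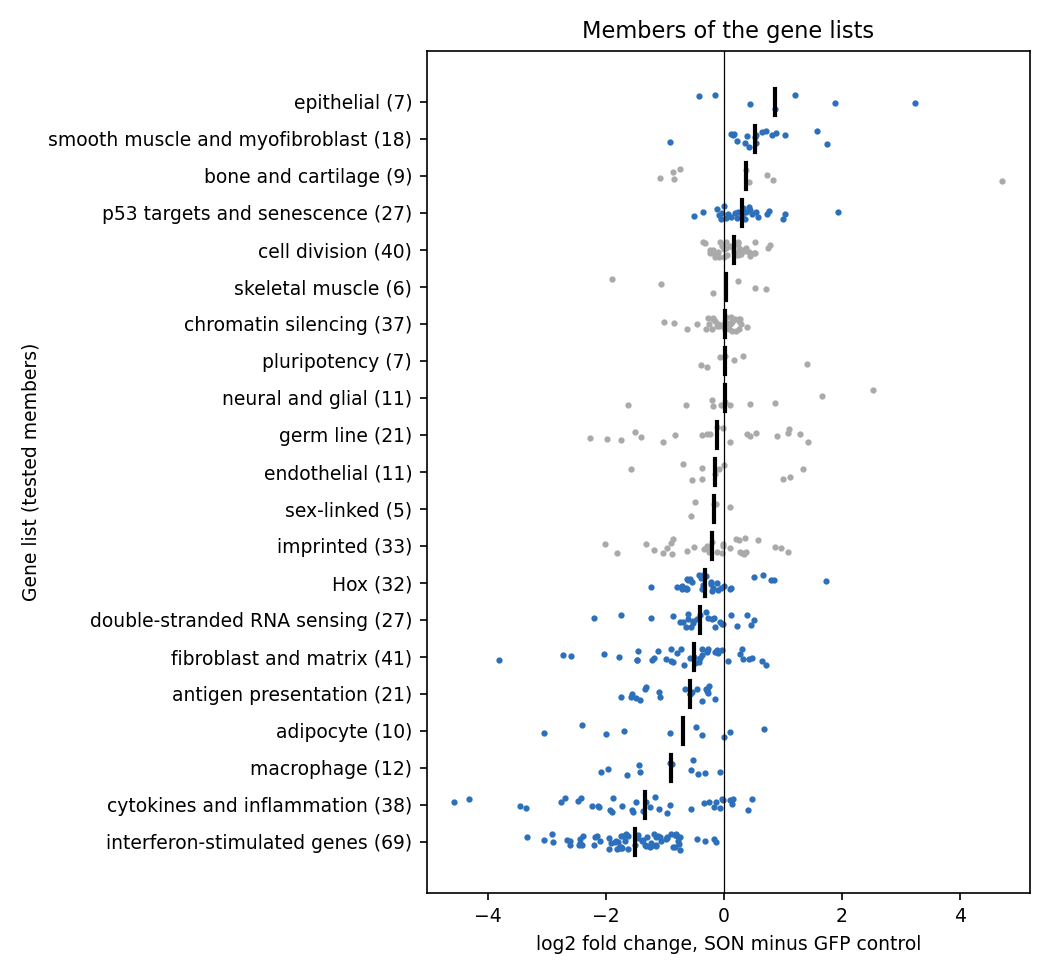
Log2 difference of SON and GFP control for every tested member of 21 gene lists, 1 dot per gene and a black bar at the list median, blue where limma camera gave an adjusted p under 0.05 with the preset correlation. All 69 interferon-stimulated genes lie below 0, with a median of -1.50.

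Genes of fibroblasts and their matrix had a median of -0.51 over 41 members, 33 of them negative (limma camera adjusted p = 6.58e-05, and with an estimated correlation adjusted p = 0.756). Of these, 4 were lower adjusted over the list alone, 0 passed limma over all genes (1 higher and 11 lower unadjusted), and the authors' deposited table calls 8 lower. The proteoglycans Lum and Dcn measured 19245 ± 18661 and 999 ± 150, and 62545 ± 38100 and 9417 ± 1025. Pdgfra, a receptor for platelet-derived growth factor, measured 12243 ± 5136 and 3428 ± 535, and Postn, a matrix protein, 98906 ± 71655 and 21237 ± 6703. Fn1, the gene of fibronectin, measured 137740 ± 5435 and 192220 ± 21848. The median difference between GFP control I and GFP control II was 0.65, and the list's median was -0.21 without GFP control I, -0.78 without GFP control II and -0.24 without SON II.

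Markers of fat cells had a median of -0.70 over 10 members, 7 of them negative (limma camera adjusted p = 0.00576, and with an estimated correlation adjusted p = 0.583). Of these, 2 were lower adjusted over the list alone, 0 passed limma over all genes (4 lower unadjusted), and the authors' deposited table calls Lpl and Fabp4 lower. The median was -0.45 without SON II. Lpl, the lipase of circulating triglycerides, measured 9420 ± 7795 and 931 ± 151, and Fabp4, a fatty acid carrier, 847 ± 0.91 and 169 ± 78.9. Macrophage markers were lower for all 12 members, with a median of -0.90 (limma camera adjusted p = 0.00304, and with an estimated correlation adjusted p = 0.756). The macrophage median was -0.23 without SON I, which ended the call (limma camera adjusted p = 0.806), and -1.60 without SON II (limma camera adjusted p = 3.12e-08). None of the 12 passed limma over all genes or adjusted over the list alone (2 lower unadjusted), and the authors' deposited table calls 0. Cd53, a leukocyte membrane protein, measured 482 ± 78.2 and 288 ± 176. Hox genes, which set position along the body axis, had a median of -0.33 over 32 members, 24 of them negative (limma camera adjusted p = 0.00900, and with an estimated correlation adjusted p = 0.583). No Hox gene passed limma over all genes or adjusted over the list alone (6 lower unadjusted), and the Hox median was -0.36 without GFP control II (camera adjusted p = 0.0921) and -0.16 without SON II (camera adjusted p = 0.170). Hoxd3, the Hox gene that the authors' deposited table calls lower, overlaps other Hox genes. Its level was 256 ± 5.46 and 109 ± 23.3, and that of Hoxb9 was 1569 ± 0.065 and 1195 ± 6.90.

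Of the 21 lists, 3 were called higher by camera. Contractile genes of smooth muscle and myofibroblasts had a median of 0.53, with 17 of 18 members positive (limma camera adjusted p = 0.0106, and with an estimated correlation adjusted p = 0.756). This rested on SON I: without it the median was -0.16 and the camera adjusted p was 0.302. Acta2, smooth muscle actin, measured 234240 in SON I and 63378 in SON II against 78587 ± 10465 in the GFP control, and Myh11, smooth muscle myosin, 15017 and 2776 against 1936 ± 314. Myh11 is the 1 member of the list that the authors' deposited table calls higher. Epithelial genes had a median of 0.86 over 7 members (limma camera adjusted p = 0.0204, and with an estimated correlation adjusted p = 0.583), and GFP control I lay below GFP control II with a median difference of -1.15. Without GFP control I the epithelial median was 0.79 (camera adjusted p = 0.0907), and without SON II it was 1.15 (camera adjusted p = 0.0845). Dsp, the desmosome protein desmoplakin, measured 54.1 ± 50.5 and 459 ± 333, and Krt19, a keratin, 105 ± 21.1 and 246 ± 69.1. Both are called higher in the authors' deposited table. Targets of p53 and genes of senescence had a median of 0.31 over 27 members, 21 of them positive (limma camera adjusted p = 0.00192, and with an estimated correlation adjusted p = 0.583). Their median was 0.12 without SON II (camera adjusted p = 0.0917) and 0.15 without GFP control I. Tnfrsf10b, a death receptor and the 1 member called higher in the authors' deposited table, is a target of p53. It measured 1769 ± 368 and 3489 ± 65.6. Of the members of these 3 lists, 0 passed limma over all genes or adjusted over the list alone, with 0, 3 and 4 higher at an unadjusted p.

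**Figure D3:**
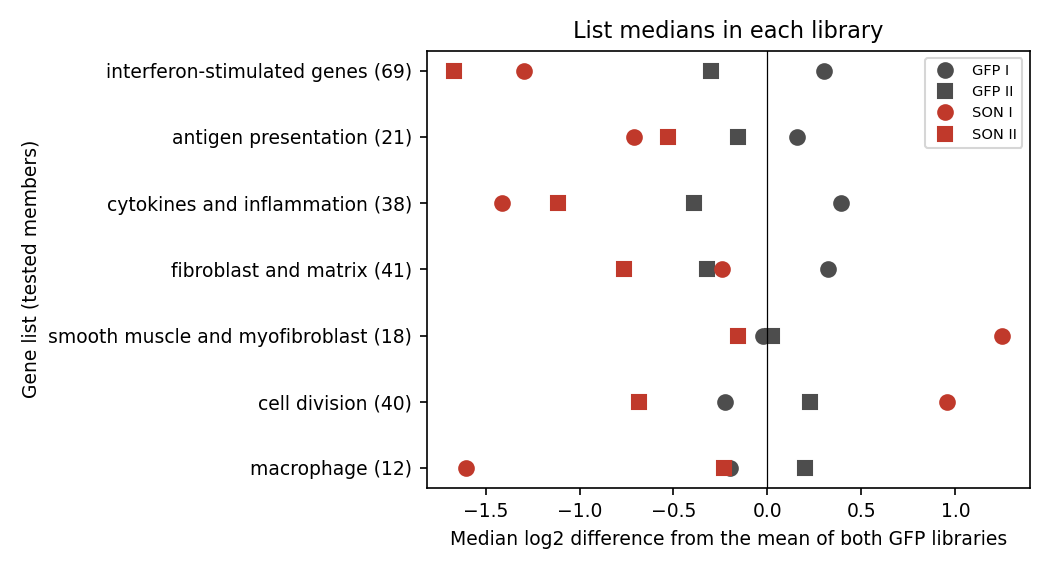
Median log2 difference of 7 gene lists in each library from the mean of the 2 GFP control libraries, 1 point per library. Interferon-stimulated genes lie at -1.30 in SON I and -1.67 in SON II, whereas smooth muscle genes lie at 1.25 in SON I and -0.16 in SON II.

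Of 32 pluripotency genes, 7 had enough reads to be tested, with a median of 0.02 (limma camera adjusted p = 0.574). The other 25 had mean values of at most 11.8. Klf4, a transcription factor also present in fibroblasts, measured 1411 ± 17.6 and 1777 ± 202. Of 50 germ line genes, 21 were tested, with a median of -0.12 (limma camera adjusted p = 0.693). The authors' deposited table calls Prdm1, Gfra1 and Bcl6b lower and Uchl1 higher. Prdm1, the repressor Blimp1, measured 760 ± 330 and 165 ± 97.7, and Gfra1, a receptor for GDNF, 3385 ± 2515 and 766 ± 329. Bcl6b, a transcription factor of spermatogonial stem cells, measured 161 ± 61.0 and 54.9 ± 11.1, and Uchl1, a deubiquitinase, 494 ± 254 and 1251 ± 285. In both lists 0 genes passed limma over all genes or adjusted over the list alone, with 1 pluripotency gene higher and 3 germ line genes higher and 6 lower at an unadjusted p.

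The remaining lists were not called. Genes of cell division had a median of 0.18 over 40 members (limma camera adjusted p = 0.167), at 0.96 in SON I and -0.69 in SON II. Their camera adjusted p was 5.23e-17 with a higher median without SON II, 0.00755 with a higher median without GFP control II, and 5.43e-08 with a lower median without SON I. Top2a, a topoisomerase of dividing cells, measured 5323 in SON I and 1334 in SON II against 2706 ± 434. Chromatin silencing genes had a median of 0.02 but a mean of -0.05 over 37 members (limma camera adjusted p = 0.739). The camera adjusted p was 0.0430 on the lower side without SON I. Trim28, a corepressor of retroelements, measured 5671 ± 6.68 and 5803 ± 1005. Zc3hav1, an antiviral RNA-binding protein and the 1 chromatin silencing member called lower in the authors' deposited table, acts on RNA. Its level was 3298 ± 575 and 1826 ± 85.9. Imprinted genes had a median of -0.20 over 33 members (limma camera adjusted p = 0.478), with the noncoding RNA Rian at 15148 ± 487 and 18196 ± 7603. Endothelial genes had a median of -0.15 over 11 members (limma camera adjusted p = 0.739). Flt1, a receptor for VEGF, was lower adjusted over the list alone, at 959 ± 165 and 322 ± 42.1, and Eng, which binds TGF-beta, measured 1188 ± 125 and 1185 ± 88.3. Neural and glial genes had a median of 0.01 over 11 members (limma camera adjusted p = 0.599). Map2 was higher adjusted over the list alone and Gap43, a growth cone protein, lower, at 1530 ± 24.1 and 504 ± 115, and the filament gene Nes measured 2209 ± 49.8 and 3602 ± 2857. Skeletal muscle genes had a median of 0.03 but a mean of -0.28 over 6 members (limma camera adjusted p = 0.971), with the acetylcholine receptor gene Chrna1 at 30.9 ± 11.8 and 49.7 ± 6.61. Bone and cartilage genes had a median of 0.37 over 9 members (limma camera adjusted p = 0.489), Col2a1 being the member called by limma.

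Transcripts of both sexes were present in both groups. Xist, the RNA of the inactive X chromosome, measured 6749 ± 1291 and 7213 ± 662. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d measured 1432 ± 522 and 936 ± 64.2, 840.0 ± 46.4 and 747 ± 59.3, 327 ± 82.7 and 230 ± 50.9, and 257 ± 52.96 and 235 ± 60.6. The 5 tested members had a median of -0.17 (limma camera adjusted p = 0.282, and 0.0484 on the lower side without GFP control II).

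LTR retrotransposons, the descendants of integrated retroviruses, were compared in the table of repeats, in which the 2 columns of each group are named a and b. Reads of the VL30 family, mouse elements related to leukemia viruses, were lower in SON. The internal sequence MMVL30-int fell from 6060 ± 202 to 3028 ± 754 (log2 -1.02, limma adjusted p = 0.0180), with 91 of its 97 copies lower. RLTR6_Mm, an LTR of the VL30 family, fell from 1205 ± 11.6 to 512 ± 139 (log2 -1.26, limma adjusted p = 0.0180), with 11 of 12 copies lower. RLTR34D_MM, with 1 of 2 copies lower, fell from 615 ± 63.6 to 223 ± 4.46 (log2 -1.45, limma adjusted p = 0.00762), and MER68B, with 3 of 6 copies lower, from 1022 ± 105 to 444 ± 26.8 (log2 -1.20, limma adjusted p = 0.0138). Of 469 LTR names, limma called 0 higher and 4 lower (10 and 52 unadjusted) on the scale of the deposited values. With TMM factors, which moved the median of all repeat names from -0.12 to 0.01, the 4 names were at -0.89, -1.13, -1.32 and -1.06 and were no longer called (limma adjusted p = 0.126, 0.126, 0.0592 and 0.0592). The calls depended on which library was left out. Over all settings, each library left out among them, the log2 difference stayed between -1.28 and -0.77 for MMVL30-int and -1.54 and -0.98 for RLTR6_Mm. It stayed between -1.56 and -1.32 for RLTR34D_MM and -1.30 and -1.06 for MER68B.

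**Figure D4:**
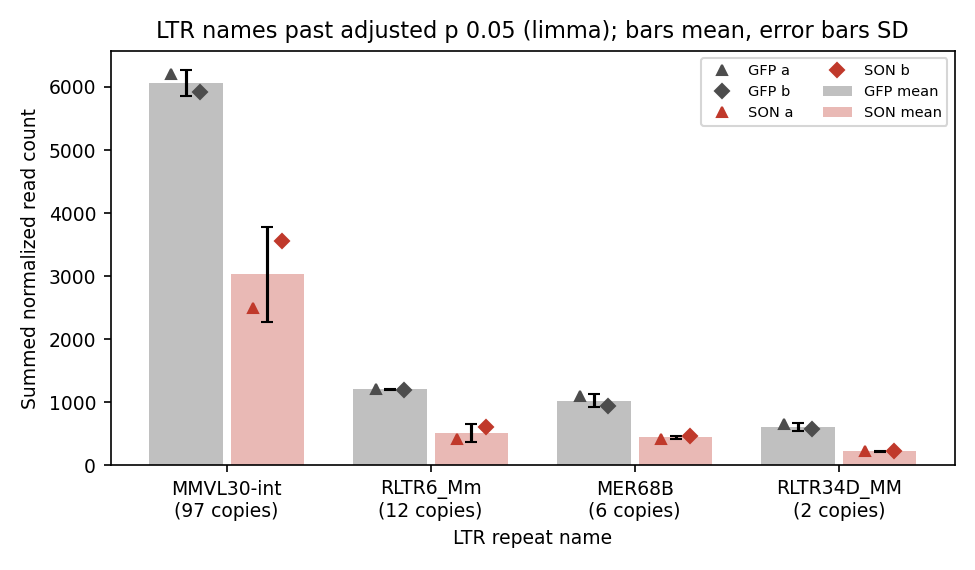
Normalized read counts of the 4 LTR names that passed limma at an adjusted p under 0.05 on the deposited scale, summed over their copies, with bars at the group means, error bars of 1 SD and points for the libraries a and b. MMVL30-int lies at 6060 in the GFP control and 3028 in SON.

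The median LTR name stood at -0.19, with 343 of 469 negative, and at -0.06 with TMM factors. Reads of young and active elements, among them the IAP, ETn, MERVL and VL30 families, summed to 24479 ± 1042 and 19133 ± 524. Of the 58 such names tested, 44 were negative with a median of -0.31, 2 were called lower by limma (the VL30 names) and 3 adjusted over the list alone. The sums for the IAP names were 1358 ± 57.7 and 1288 ± 83.0, and those for the MERVL names 2781 ± 292 and 2407 ± 400. Names of the RLTR9, RLTR13 and RLTR17 groups summed to 7851 ± 645 and 6681 ± 700. Of 32 tested, 22 were negative with a median of -0.21, limma called 0 (2 lower unadjusted), and 1 was lower adjusted over the list alone. Among 3843 single LTR copies limma called 0 (128 higher and 345 lower unadjusted, 192 by chance), edgeR 0 and DESeq2 25 lower. Limma called 45 higher and 182 lower without SON a, 36 and 319 without SON b, 3 and 38 without GFP control b, and 0 without GFP control a. Ribosomal RNA took 2.66 ± 0.96% of the reads in repeats in the GFP control and 15.1 ± 10.2% in SON, and LTR elements 24.04 ± 0.31% and 19.9 ± 2.56%. Of the reads outside ribosomal RNA, LTR elements took 24.7 ± 0.077% and 23.4 ± 0.21%.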

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

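The test of single 28S copies was chosen after the share of ribosomal RNA had been seen.

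Ribosomal RNA in the repeat table, which lies outside the comparison of LTR elements, held a larger share of the reads in SON than in the control libraries. The mean share was 15.1% in SON against 2.66% in the GFP control, or 22.3% (Wilson 95% interval 22.2 to 22.4) and 7.85% (7.78 to 7.93) in the SON libraries and 1.97% (1.95 to 2.00) and 3.34% (3.31 to 3.37) in the GFP control libraries. The intervals cover counting error only, and the SON libraries differed from each other by far more. Summed over copies, the 28S sequence LSU-rRNA_Hsa rose from 17970 ± 5778 to 111910 ± 82284 and the 18S sequence SSU-rRNA_Hsa from 108 ± 18.0 to 674 ± 337 (n = 2, limma adjusted p = 0.0180 and 0.00762). With TMM factors neither passed (limma adjusted p = 0.221 and 0.126), although the log2 differences were 2.58 and 2.66 in place of 2.45 and 2.54. Over all settings, each library left out among them, the log2 difference ranged from 1.62 to 3.28 for 28S and from 2.01 to 3.07 for 18S.

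Of the 28S copies, 95.7% (45 of 47) were higher in SON, so the direction was not limited to a few copies. That count cannot tell how much of the summed rise a few copies held, so this stays open. How reads with several hits were counted is not given, so the copies cannot be taken as independent. The median log2 difference was 0.015 over 60 small nuclear and nucleolar RNA genes, with 34 positive and 26 negative. That argues against more untailed RNA in SON for these genes only. Rn7sk, at 10.4 ± 2.92 and 125 ± 77.4, and the repeat name U3, at 1.49 ± 2.10 and 38.7 ± 6.83, were higher in SON. More untailed RNA of other kinds stays open. Ribosomal RNA left in the SON libraries and a change in ribosomal RNA within the SON cells both stay open, since either could raise the genes that hold a ribosomal sequence, which had a median log2 difference of 2.28, with Lars2 at 8804 ± 3058 and 50692 ± 41472 and Gm42418 at 22118 ± 5130 and 129880 ± 104830 (n = 2). That median rests on 3 of 6 such genes and was 1.35 without SON I. No value separated these explanations, and the biological one was not tested.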

How the results depend on the processing

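Limma with TMM factors, the block in limma, DESeq2 without a library and the repeat table without ribosomal RNA were chosen after the data had been seen. EdgeR with TMM factors was the main test fixed for raw counts, and only its use on the recovered reads was chosen later.

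With all 4 libraries, the 8 called genes kept their direction, and they stayed past the threshold in 87 gene and setting combinations and missed it in 9. These were Dppa3 and Nanos2 with pseudocount 0.1, Col2a1, Igfbp2, Fmo2 and Cxcl3 with voom, Igfbp2 and Cxcl3 with upper-quartile factors, and Igfbp2 with the block in limma. With a library left out they stayed past it in 5 and missed it in 27. Genes higher were 3 with pseudocount 0.1, 236 with DESeq2 and 3 with voom. Genes lower were 381 with DESeq2 and 1 with voom. Taking the shared numerals as a block, genes lower were 7 in limma and 10 in edgeR, although the deviations of libraries with the same numeral correlated at only 0.22 in 2 pairs. Leaving out a library gave 0 to 8 genes higher and 0 to 24 lower. Camera with an estimated correlation called 0 lists higher and 0 lower (lowest adjusted p = 0.583), and fry 0 and 0 (lowest adjusted p = 0.174), against 3 and 8. The cause was not tested for any of these.

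LTR copies lower were 25 with DESeq2. Leaving out a library gave 0 to 45 copies higher and 0 to 319 lower. LTR names lower were 12 with DESeq2, 2 with upper-quartile factors, and 0 with voom, RLE factors, edgeR with TMM factors, limma with TMM factors and without ribosomal RNA, against 4. Leaving out a library gave 0 to 1 names higher and 0 to 13 lower. The cause was not tested. No paired analysis of repeats was made because no label gives their columns a numeral, and scaling them by the gene table was not run for the same reason.

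The 24 genes that the naming rule took without a call stayed so with the same sign in 272 combinations with all 4 libraries, were called in 5 and changed sign in 11. With a library left out these counts were 83, 1 and 12. The cause was not tested. The 6 named repeat names stayed past the threshold in 32 combinations with all 4 libraries and missed it in 32, and with a library left out in 12 and 12, all with the same sign. Sign changes were as follows. Top2a was at 0.30 with DESeq2 and RLE factors, 0.29 with upper-quartile and TMM factors in edgeR, and between -1.01 and 0.99 with a library left out. Eng was at 0.0060 with DESeq2 and RLE factors, 0.0017 with voom and with the block in edgeR, 0.0027 with upper-quartile factors, 0.00097 with TMM factors in edgeR and 0.0014 in limma, and between -0.11 and 0.11 with a library left out, a difference too small to carry a sign. With a library left out, Calr ranged from -0.34 to 0.032, Acta2 from -0.30 to 1.58, Trim28 from -0.16 to 0.20, Rian from -0.24 to 0.64, Nes from -0.48 to 1.35, Xist from -0.090 to 0.30 and Kdm5d from -0.40 to 0.13. Libraries that were left out leave 1 sample in a group, which is then assumed to vary like the other group. At this depth no difference was detectable in the 13132 genes without reads, and 25 pluripotency and 29 germ line genes lay below the filter and were not tested.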

Other observations

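The list of hypoxia genes was written after 5 of its genes had been seen, and the tests of interferon-stimulated genes and of the scaling of VL30 were chosen after the results were seen.

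Genes of the response to low oxygen lay mostly lower in SON. The 5 genes that prompted the list were Adm, Bnip3, Egln3, Stc2 and Ndufa4l2, and 37 others were tested without them. Of these, 35 were negative with a median log2 difference of -0.56, 20 were lower adjusted over the list alone, 0 passed limma over all genes (1 higher and 23 lower unadjusted, lowest adjusted p = 0.230), and the authors' deposited table calls 9 lower. Ldha, lactate dehydrogenase, measured 34575 ± 3016 and 23378 ± 1152 (GFP control and SON, mean ± SD, n = 2). Pdk1, a kinase that inhibits pyruvate dehydrogenase, measured 1877 ± 44.8 and 937 ± 117. Vegfa, a growth factor of blood vessels, measured 5550 ± 1137 and 3197 ± 327. Pfkfb4, a regulator of glycolysis, was an exception at 201 ± 1.69 and 343 ± 21.9. The limma camera p was 3.33e-15 with the preset correlation and 0.121 with an estimated correlation, and the fry p was 0.0411. A weaker response to low oxygen, or a lower cell density in the SON dishes, may lie behind the shift, and neither was measured. The median lay between -0.70 and -0.47 with each library left out, and GFP control I and II differed by a median of 0.03.

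The SON libraries differed from each other in other lists. The median difference of SON I and SON II was 1.66 in cell division genes, 1.41 in smooth muscle genes and -1.75 in macrophage markers. Between GFP control I and II it was 0.65 in fibroblast genes, 0.78 in cytokines and -1.15 in epithelial genes.

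Interferon-stimulated genes lay lower in SON, with a median of -1.50. A difference carried by GFP control I alone is argued against, since the median was -1.17 without it. Scaling moves all genes of a library alike, so it is argued against by the position of the list relative to the median of all tested genes, which was -1.50. Fewer macrophages among the SON cells were weighed by the summed fall of their markers, 0.754% of that of the interferon-stimulated genes. This share cannot decide, since the markers summed to only 1553 in the GFP control and 918 in SON, against a fall of 84185. It would stay small even if every marker were lost. The medians of both lists moved in opposite directions within each group (0.60 and -0.40 for GFP control I and II, 0.44 and -1.75 for SON I and II). That argues against macrophages as the whole cause, although all 12 markers were lower in SON. An effect of the delivered genes, a different response to each virus stock, and differences between cultures stay open, as the design does not separate them.

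Reads of VL30 elements lay lower in SON. Scaling by ribosomal RNA is argued against as the whole cause, since MMVL30-int lay at -0.83 relative to the median of all LTR names, and the size factors of the repeat table (1.20, 1.68, 0.736 and 0.680) were close to those of the gene table (1.20, 1.68, 0.733 and 0.681). Its call ended without ribosomal RNA, where it was at -0.89 ± 0.13 (SE, limma adjusted p = 0.115) in place of -1.02 ± 0.17 (SE, limma adjusted p = 0.0180). The fold was smaller but the difference was larger relative to its SE, so the smaller fold does not account for the larger p. Why the p grew was not tested further. A fall in a few copies is argued against, since without the 5 copies with the most reads, which held 43.7% of the GFP control reads of MMVL30-int, the sum fell by 1.25 on the log2 scale. An effect of the delivered genes was not tested and stays open.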
